A study of Mus musculus with 6 samples.

How the data were processed

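Total RNA of footpad skin from BALB/c nude mice, 3 injected with Mycobacterium leprae and 3 with phosphate-buffered saline, was extracted with TRIZOL and labelled with biotin by the MessageAmp kit for Illumina arrays, per the labels' protocols. The authors deposited 2 tables of the same 6 arrays. The first holds, per the file headers, a mean bead intensity for each probe on each array, on a linear scale and not normalized, with a detection p-value for each. How the authors' software computed the deposited detection p-value is not given in the sources used here. The second is the authors' table of processed values. BeadStudio, Illumina's software for these arrays, is named in the submitters' processing notes without a version, and the normalization behind the deposited intensity values of the second table is not given in the sources used here. Each column of that table correlated across probes with 1 scanner column at 0.998 or more on the log2 scale, and column medians lay between 126.52 and 127.48, so the scale was taken as linear.

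Columns of the first table carry the group and a letter but no replicate number, so the arrays are called control A, B and C and infected A, B and C. A column of the second table was matched to its group and replicate number by its sample. The files hold no chip or slide position, so no batch could be tested and a fit with the chip as a block could not be run.

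Of 46632 rows, 785 had no value on at least 1 array and were left out, 11 of them with a value on control A alone. Of the remaining 45847 rows, 8266 (18.0%) repeated the values and detection p-values of another row exactly, and each set of identical rows was used as 1 row, which left 37581 distinct rows. Gene names came from the platform annotation of 29986 probes, updated to current symbols through the RefSeq gene table of assembly GRCm38.p6, where 29933 probes matched (29921 by gene number and 12 by accession). Of the distinct rows, 22377 had 1 gene, 125 had several and were left unnamed, and 15079 are unnamed here. No genome build is given by the files, and no coordinates are given here.

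Values were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe was kept if its detection p was under 0.05 on at least 3 of the 6 arrays, which left 14200 distinct probes, 10462 of them with 1 gene. Of several probes of a gene the one with the highest mean over all arrays was used, which gave 9142 genes of 17249 on the array. Of 1083 genes with several detected probes, 134 had all probes called in the same direction, 582 had none called, 355 had some called and some not, and 12 had probes called in both directions. Infected and control arrays were compared with limma's linear model and moderated test (lmFit, and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Where a probe was detected on no array of 1 group, the fold is given as a bound. Median scanner signals ranged from 112.67 to 144.14 over the arrays, and probes near background show compressed fold changes. Probes of near-identical gene families, such as hair keratins, can share signal.

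There were 34 gene lists, with 697 memberships of which 457 were tested, written from textbook knowledge of skin, muscle, nerve, leukocytes and infection. Each was tested with camera of limma with a preset correlation of 0.01, against all other genes, with Benjamini-Hochberg adjustment over the lists. The count of members adjusted over the list alone applies Benjamini-Hochberg within that list. The groups, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where added alternatives are named. The rule took the 6 genes with the highest and the 6 with the lowest log2 fold change among those that passed with no overlap between groups, leaving out symbols that are only clone or locus numbers. From each list it took the 2 (or, for lists of tissue context, 1) members with the largest change that passed likewise. Collapsing identical rows was decided after the rows were seen, and keeping them is an added alternative.

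The steps were tested on simulated data for the comparison of infected with control arrays. These were made from the real means and the moderated residual SDs (after eBayes) of 9142 genes. In them 200 single genes were changed and a list of 15 others was shifted up by 1 on the log2 scale, which camera found. Noise was drawn independently for each gene, so the simulation does not test the calls of lists whose genes are correlated. Estimated correlations of the real lists reached 0.795, for skeletal muscle. Of 100 genes changed by 1 on the log2 scale 12.0% were recovered, of 100 changed by 2 on the log2 scale 78.0% were recovered, and 4 of the other 8927 genes, which were unchanged, were called. Far fewer genes were changed there than the 3437 called in the data, which makes the adjusted threshold stricter. Both groups were also given the same SD for a gene. The recovery rates therefore do not measure the sensitivity of the real comparison. Alternatives covered the background correction, the scaling between arrays, the detection filter, the choice of probes, the variance trend, array weights, the authors' processed values, the threshold, a fold threshold inside the test, the correlation between genes of a list, other tests of lists, and leaving out each array. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.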

Results

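RNA of footpad skin was measured on 6 Illumina mouse BeadChip arrays. The mice were BALB/c animals homozygous for the nude mutation of Foxn1, which leaves them without a functional thymus and with few mature T cells. Footpads of 1 group had received a subcutaneous injection of 2000000 Mycobacterium leprae, the bacterium that causes leprosy, and those of the other group an injection of phosphate-buffered saline. Skin was taken 12 months after the injection, 3 biological replicates per group, 1 array each, and the replicates were grown and harvested separately according to the series' design text. Between 33.0% and 37.7% of the distinct probes were detected on each array, and 9142 named genes entered the comparison. The single comparison asks how gene expression of the infected footpad, described by the series title as a granuloma, differed from that of the injected but uninfected footpad.

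Infected skin carried higher levels of genes of macrophages, of interferon responses and of antigen presentation than control skin, and lower levels of genes of hair, skeletal muscle and fat. These are calls of gene lists with a preset correlation between genes, and with an estimated correlation no list was called by camera (smallest adjusted p = 0.0578, with 12 lists up and 1 down at an unadjusted p under 0.05). In all, 1643 genes were higher and 1794 were lower in infected skin, and 1314 and 1357 of these differed at least 2-fold. Among the 6 largest fitted rises of named genes was that of Clec4e, a receptor for mycobacterial cord factor, whose probe was detected on no control array and was at least 82.8-fold higher in infected skin. Ccl5, a chemokine that attracts T cells and monocytes, rose by 6.50 ± 0.30 on the log2 scale (SE, n = 3 per group). Hair keratin Krt33b fell by 6.52 on the log2 scale (SE 0.84), and Lyg1, a lysozyme-like gene detected on no infected array, was at least 61.7-fold lower. Such a bound sets the mean of the brighter group against the lowest signal that counted as detected on each array of the dimmer group. Where the probe's own signal was higher, that signal was used. The bound concerns the fold between group means and makes no allowance for the spread among arrays. Infected log2 signals of Clec4e, for example, were 11.295, 12.242 and 13.276.

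Besides Clec4e and Ccl5, the 6 largest fitted rises included Ubd, an interferon-inducible ubiquitin-like modifier (log2 fold change 6.50 ± 0.30), Il1rn, the antagonist of the interleukin-1 receptor (6.37 ± 0.31), F10, coagulation factor X (6.23 ± 0.46), and Fcgr4, an activating receptor for antibodies (6.16 ± 0.30). Among the 6 largest fitted falls were Spink6, an epidermal protease inhibitor that fell by 6.53 on the log2 scale (SE 0.37), and the hair genes Krtap6-2 and Krt34, which fell by 6.47 (SE 0.80) and 6.14 (SE 0.86). Krt90, a keratin detected on no infected array, was at least 63.2-fold lower. By the rule that chose these 12 genes, all passed and the 3 infected values of each lay beyond all 3 control values. Their adjusted p lay between 4.77e-05 and 0.00159 by the moderated test. The fitted log2 fold change of Krt90 was -7.14 without control A, against -6.20 with it. Those of Krt33b, Krtap6-2 and Krt34 were -5.85, -5.66 and -5.45 without control A, and -7.63, -7.45 and -6.88 without control B. Without infected B, that of Krt34 was -6.93. A second probe for Il1rn was detected on 0 of 6 arrays. The probes used for Ubd and Il1rn were each detected on 1 of 3 control arrays, and that for F10 on 2. Those for Krt33b and Krtap6-2 were each detected on 1 of 3 infected arrays, and that for Spink6 on 2. Control means of Ubd and Il1rn (5.91 and 5.67) and infected means of Krt33b and Krtap6-2 (5.26 and 5.51) lay near or below the lowest detected signals. Those were 5.71 to 6.02 over the arrays, so these 4 fitted changes rest on signal near background.

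**Figure D1:**
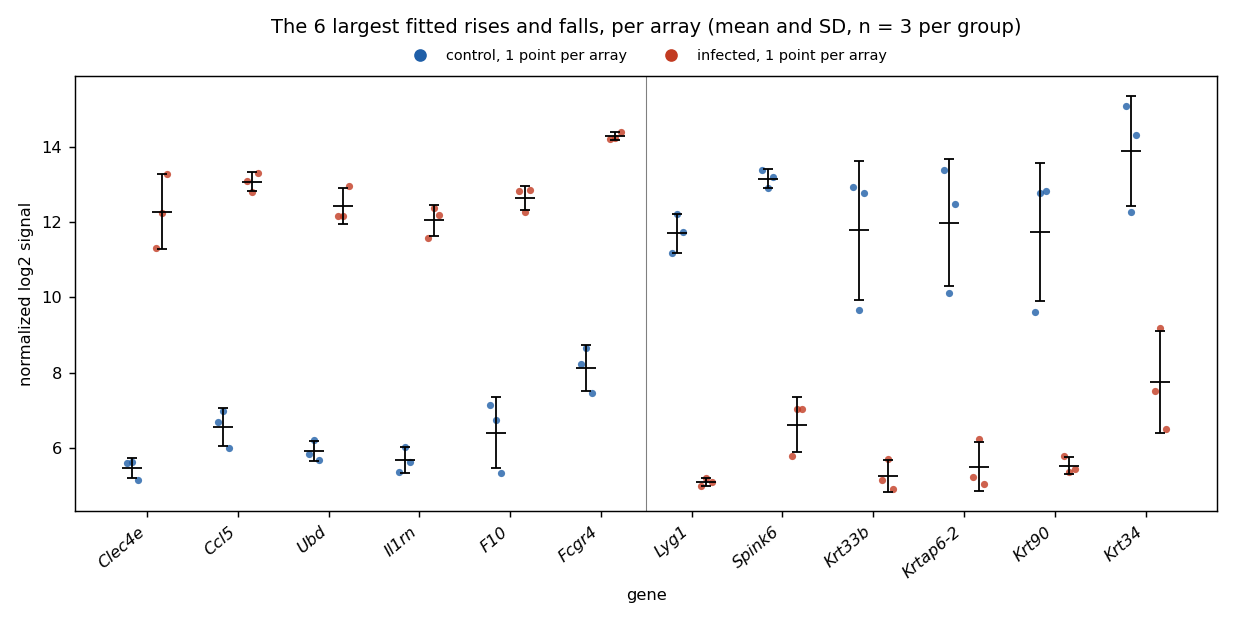
Normalized log2 signal (vertical axis) of the 6 genes with the largest fitted rises (left) and the 6 with the largest fitted falls (right), 1 point per array, controls in blue and infected in red, with mean and SD (n = 3 per group). Infected means of the rising genes lay between 12.04 and 14.28, against control means between 5.47 and 8.11.

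1 control array stood apart from the other 2. Correlations across genes were 0.893 and 0.889 between control A and controls B and C, 0.968 between controls B and C, and 0.978 to 0.983 among the infected arrays. On control A, 190 genes lay at least 8-fold below the mean of the other 2 controls and 1 lay at least 8-fold above, while the largest such count of low genes on another array was 22, on control B. The first principal component, 72.7% of the variance, separated the groups, and the second, 18.2%, separated control A from controls B and C. Without infected C, 1173 genes were higher and 1156 lower. Without control A, 2235 genes were higher and 2185 lower, and 3382 of the 3437 genes called with it were called in the same direction. Values of some genes with low signal on control A moved without that array: H2-Ab1, a chain of the MHC class II molecule, went from 5.62 ± 1.56 to 3.65 on the log2 scale, and the immunoproteasome subunit Psmb8 from 5.66 ± 1.01 to 4.39.

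**Figure D2:**
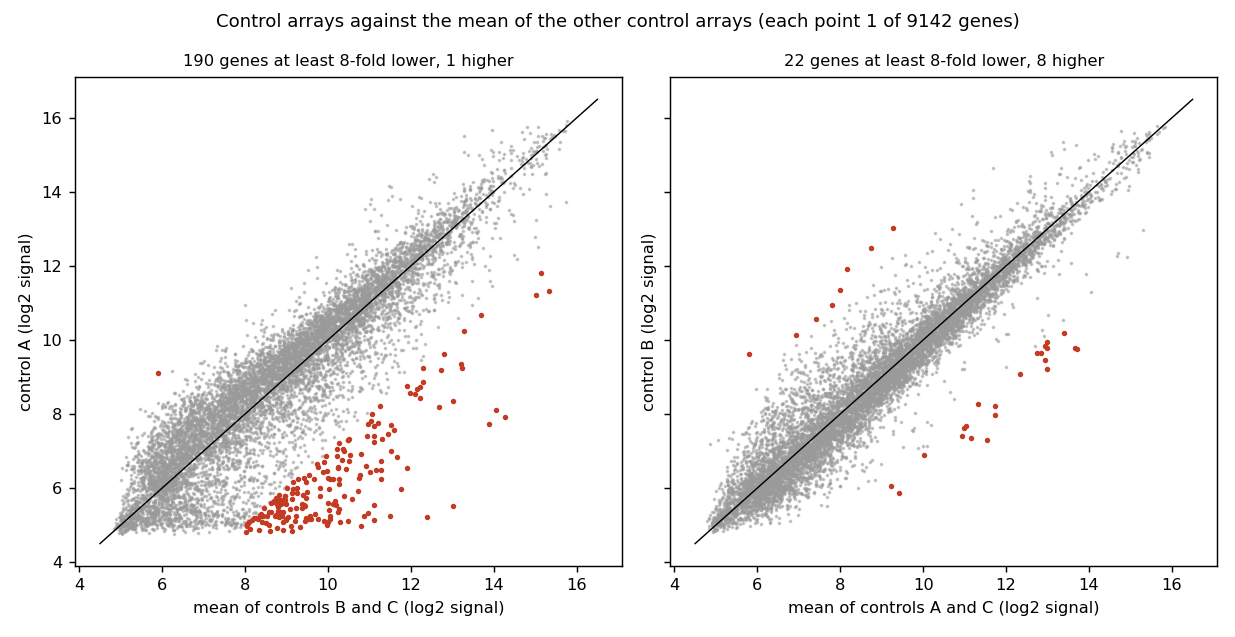
Normalized log2 signal of control A against the mean of controls B and C (left) and of control B against the mean of controls A and C (right), 1 point for each of 9142 genes, with the line of equality. Red points are genes at least 8-fold away from that line: 190 below and 1 above for control A, 22 below and 8 above for control B.

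Macrophage genes were higher in infected skin. All 16 tested members of the macrophage and myeloid list rose, 16 also when adjusted over the list alone, with a median log2 fold change of 3.82. Mpeg1, a pore-forming protein of macrophages, was detected on no control array and was at least 26.8-fold higher (adjusted p = 4.77e-05), and Aif1, a calcium-binding protein of macrophages, rose by 4.79 ± 0.35 (adjusted p = 0.000132). The list was shifted up against the other genes (camera, adjusted p = 2.91e-12; adjusted p = 0.0578 with an estimated correlation). Of 19 lysosomal genes, which encode enzymes and membrane proteins of the degradative compartment, 18 rose, 18 also when adjusted over the list alone, and Lamp2 did not pass (log2 fold change 0.10). The carboxypeptidase Ctsz rose by 4.53 ± 0.18, and beta-glucuronidase, Gusb, was at least 12.6-fold higher. A second Gusb probe, detected on 3 arrays, had a log2 fold change of 1.204. The lysosomal list had a median of 2.24 (adjusted p = 2.12e-11; adjusted p = 0.0578 with an estimated correlation).

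Lipid handling genes moved in both directions. In the list for lipid uptake and storage, 10 of 14 members rose, 1 fell and 3 did neither, and adjusted over the list alone 10 rose and 2 fell. Without control A, 9 rose and 2 fell. Trem2, a lipid-binding receptor of macrophages, rose 29.9-fold, and the scavenger receptor Msr1 rose by 3.53 ± 0.35 on the log2 scale (a second Msr1 probe was detected on 0 of 6 arrays), while the apolipoprotein gene Apoc1 fell by 1.80. The list's median was 1.57 (adjusted p = 0.0111; adjusted p = 0.129 with an estimated correlation). Genes of alternative macrophage activation were not shifted as a list (median 1.08, adjusted p = 0.099, or 0.391 with an estimated correlation). Without infected A the median was 0.10 (adjusted p = 0.331). With the preset correlation the list was called without infected B (1.40, adjusted p = 0.0401) and without infected C (1.62, 0.0264). It was also called with all probes (0.0353) and with no detection filter (0.0222). Of 13 members, 4 rose and 1 fell, and the counts adjusted over the list alone were again 4 and 1. The 4 were Il1rn, Tgfb1 (3.23 ± 0.56, or 2.46 without control A), Il4ra and Mrc1, and Stab1, a scavenger receptor, fell by 1.66. Arginase Arg1, with a log2 fold change of 2.32 ± 1.33, did not pass (adjusted p = 0.213). Members named beside the rule, here and below, to spell out a small count or an exception were chosen after their values were seen.

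Interferon-inducible genes that passed the detection filter rose almost without exception. Of 19 interferon-gamma-inducible genes on the array 14 were tested, and of 19 type I genes 16. The filter could keep genes detected on the infected arrays alone, and it left out those dim in both groups. All 14 tested interferon-gamma-inducible genes rose, 14 also when adjusted over the list alone, with a median of 3.63 (adjusted p = 1.05e-10; adjusted p = 0.115 with an estimated correlation). Cxcl9, a chemokine induced by interferon-gamma, was detected on no control array and was at least 27.7-fold higher, and Cd274, the ligand of the PD-1 receptor, rose by 4.96 ± 0.31. The cytokine gene Ifng itself, also detected on no control array, was at least 4.63-fold higher (adjusted p = 0.000135). Of 16 genes of the type I interferon list, 14 rose, 14 also when adjusted over the list alone, and Oas1g (2.84 ± 1.46) and Ifi35 (1.12 ± 0.87) did not pass. Ifit3 was at least 19.9-fold higher and Oasl1 at least 15.1-fold higher, both undetected on every control array. That list had a median of 2.99, or 2.75 with such genes at their bounds (adjusted p = 7.32e-09; adjusted p = 0.129 with an estimated correlation).

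Antigen presentation genes of both classes rose. In the MHC class II list 11 of 13 members rose, 11 also when adjusted over the list alone, with a median of 2.66 (adjusted p = 1.67e-06; adjusted p = 0.0578 with an estimated correlation). H2-DMb1, a chain of the peptide exchange factor, rose by 4.51 ± 0.43 (3.81 for a second probe) and H2-Ab1 by 5.62 ± 1.56 (adjusted p = 0.0262). The call for H2-Ab1 was lost when any 1 infected array was left out, with adjusted p between 0.0698 and 0.0753, and its SD was 3.62 among controls and 0.21 among infected arrays. H2-Ob and Cd80 had log2 fold changes of -0.14 and -0.04. In the MHC class I list 11 of 13 members rose, 11 also when adjusted over the list alone, with a median of 2.92 (adjusted p = 9.57e-07; adjusted p = 0.0787 with an estimated correlation). Psmb8 rose by 5.66 ± 1.01 and the class I gene H2-Q7 by 3.85 ± 0.43, and H2-T10 and Psme2 did not pass.

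Cytokines, innate receptors and complement components followed. Of 19 inflammatory cytokine and chemokine genes, 17 rose and none fell, and adjusted over the list alone 18 rose and 1 fell. Besides Ccl5, Il1b, which encodes interleukin-1 beta, rose by 5.77 ± 0.53, and Il18 and Cxcl14 did not pass (-1.20 ± 0.46 and 0.56 ± 0.23). Without control A, Il18 fell by 1.73 (adjusted p = 0.000467), and 16 genes rose and 1 fell. The list's median was 3.53, or 3.38 with bounds (adjusted p = 1.25e-09; adjusted p = 0.0578 with an estimated correlation). Of 16 pattern recognition genes, 13 rose, 13 also when adjusted over the list alone, led by Clec4e and by its neighbour in the same receptor family, Clec4d (5.04 ± 0.33). Tlr5, Myd88 and Pycard did not pass. The median was 2.45, or 1.92 with bounds (adjusted p = 2.1e-07; adjusted p = 0.137 with an estimated correlation). All 8 tested complement genes, of 12 on the array, rose, 8 also when adjusted over the list alone. Among them were complement factor B, Cfb (4.10 ± 0.32), and C1qa (3.66 ± 0.86, or 2.55 without control A). The complement list's median was 2.76 (camera, adjusted p = 7.45e-06, or 0.0578 with an estimated correlation). The call for C1qa was lost without infected C (adjusted p = 0.0524).

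In the list of phagocyte oxidase and antimicrobial genes, 5 of 9 members rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone. The oxidase subunits Cybb (5.90 ± 0.47, and 4.61 for a second probe detected on 5 of 6 arrays), Ncf4 and Cyba, their activator Rac2, and Acod1, the enzyme that makes itaconate (5.78 ± 0.37), rose. The antimicrobial peptide gene Camp fell by 3.24 (by 4.27 without control A) and the vitamin D receptor Vdr by 2.02. The median was 3.66 (adjusted p = 0.0116; adjusted p = 0.257 with an estimated correlation), and without control A the list's call was lost (adjusted p = 0.084).

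Markers of lymphocytes and of other leukocytes were measured as well. Of 12 T cell markers, 9 rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone. The CD3 chains Cd3g and Cd3e, both undetected on every control array, were at least 32.03-fold and 22.01-fold higher, while Bcl11b fell by 1.18 and Cd8b1 and Cd5 did not pass (0.16 ± 0.35 and 0.88 ± 0.34). Both passed without control A (0.57, adjusted p = 0.012, and 1.15, adjusted p = 0.0161). The T cell list had a median of 1.62, or 1.02 with bounds (adjusted p = 0.000135; adjusted p = 0.257 with an estimated correlation). Of 20 NK cell and cytotoxic markers on the array, 9 passed the detection filter and were tested. Of those 9, 7 rose, 7 also when adjusted over the list alone, including the granule protein gene Nkg7 (4.74 ± 0.35) and the chemokine Xcl1 (3.91 ± 0.34). Their median was 2.39, or 1.91 with bounds (adjusted p = 2.37e-05; adjusted p = 0.115 with an estimated correlation). Of 10 B cell and plasma cell markers, 6 rose and 1 fell (7 and 1 when adjusted over the list alone). Mzb1, a chaperone of antibody-secreting cells, rose by 4.21 ± 0.56 (3.56 without control A), and the B cell receptor modulator Cd22 was at least 8.83-fold higher, with a list median of 1.27 (adjusted p = 0.00847; adjusted p = 0.177 with an estimated correlation).

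Dendritic cell markers rose in 8 of 12 cases, or 9 with 1 fall when adjusted over the list alone, and Itgax, an integrin chain also carried by macrophages, was at least 24.6-fold higher, while a second Itgax probe, detected on 3 arrays, had a log2 fold change of 1.91. Their median was 2.11, or 1.39 with bounds (adjusted p = 0.000655; adjusted p = 0.211 with an estimated correlation). Neutrophil markers were not shifted as a list (median -0.71, adjusted p = 0.775, or -1.46 and 0.112 without control A). The median was -0.21 without control B and -0.42 without control C. Of 10 members, 2 rose and 2 fell, the counts adjusted over the list alone being 2 and 2. Without control A, 2 rose and 5 fell, namely Ngp, Prtn3, Ltf, Chil1 and Il1r2. The receptor genes Csf3r (4.64 ± 0.41) and Cxcr4 rose, Ltf, which encodes lactoferrin, and Il1r2 fell, and S100a8 and S100a9 had log2 fold changes of 0.24 ± 0.64 and 0.02 ± 0.88, or -0.51 and -1.02 without control A, and passed in neither case. Among 9 mast cell markers, 5 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone. The tryptase gene Tpsab1 fell by 3.07 (SE 0.89, adjusted p = 0.0301), a call lost without control B or without control C (adjusted p = 0.0797 and 0.0669). Without infected C, Tpsab1 fell by 1.94 (adjusted p = 0.00577), and its infected signals were 8.50, 8.53 and 5.08. Hdc, the enzyme of histamine synthesis, rose by 2.02. The mast cell list's median was -1.44 (adjusted p = 0.037; adjusted p = 0.333 with an estimated correlation), a call lost without control A or without control B (adjusted p = 0.0732 and 0.0535), with array weights (0.0714) and with a stricter detection filter (0.147).

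Matrix genes and the proteases that act on them formed separate lists. In the list of extracellular matrix and fibroblast markers 4 of 20 members rose and 3 fell, with the same 4 and 3 counts when adjusted over the list alone, and the list was not shifted (median 0.43, adjusted p = 0.148). Fibronectin, Fn1, rose by 2.13 ± 0.43 and biglycan, Bgn, by 1.26 ± 0.17, while Col1a2, Lum and Sparc fell by 1.03, 0.97 and 0.90. Of 15 matrix proteases and inhibitors, 10 rose and 1 fell, 10 and 1 also when adjusted over the list alone. Mmp3, which cleaves several matrix proteins, rose by 3.49 ± 0.32, and the membrane protease gene Adam8 was at least 12.1-fold higher (a second Adam8 probe was detected on 0 of 6 arrays), with a list median of 1.83 (adjusted p = 0.000799; adjusted p = 0.0943 with an estimated correlation). Endothelial and lymphatic markers had a median of 0.45, with 6 of 21 higher and 1 lower, 6 and 1 also when adjusted over the list alone (adjusted p = 0.0444; adjusted p = 0.348 with an estimated correlation). Those that rose included the adhesion molecule Icam1 (3.28 ± 0.33), and the lymphatic receptor gene Lyve1 fell by 0.91. That list's call was lost without control C, infected B or infected C (adjusted p = 0.106, 0.065 and 0.0548), with medians of 0.26, 0.30 and 0.30, and also with cyclic loess or with all probes (adjusted p = 0.0516 and 0.0513).

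Genes of the hair and epidermis were lower in infected skin. All 13 tested hair follicle and hair shaft genes, of 18 on the array, fell, 13 also when adjusted over the list alone. Their median was -4.06 (camera, adjusted p = 9.43e-06, or 0.278 with an estimated correlation). The hair list's mean signal was 12.26, 9.45 and 12.00 on controls A, B and C, and between 6.01 and 7.61 on the infected arrays. Foxn1, the gene mutated in these mice, was itself placed in the hair list but was not among the 13 tested. Both groups carry the mutation, so the controls are not skin with normal Foxn1. Of 23 epidermal keratinocyte markers, 14 fell and none rose, and 16 fell when adjusted over the list alone. Krt15, a keratin of basal cells, fell by 3.12 (SE 0.27) and Flg2, a protein of the cornified layer, by 2.66 (SE 0.43; a second Flg2 probe, detected on 1 of 6 arrays, had a log2 fold change of -0.72), while Krt14 and Krt5, the main basal keratins, had log2 fold changes of -0.15 ± 0.14 and -0.11 ± 1.00. The keratins Krt1 and Krt2 of the upper layers and loricrin, Lor, did not pass either (0.52 ± 1.54, -0.08 ± 0.14 and 0.19 ± 0.15). Without control A, Krt5 and Krt1 fell, by 1.47 and 1.57 (adjusted p = 0.000392 and 0.00197), and 19 of the 23 markers fell. The list's median was -1.67 (adjusted p = 5.9e-06; adjusted p = 0.211 with an estimated correlation). Among 10 sweat and sebaceous gland genes 5 fell, 5 also when adjusted over the list alone, among them Awat2, an enzyme of wax ester synthesis, by 3.47 (SE 0.35). The gland list's median was -1.25 (adjusted p = 0.0413; adjusted p = 0.204 with an estimated correlation), and its call was lost without control A or with a stricter detection filter (adjusted p = 0.0518 and 0.222).

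Genes of muscle, fat, bone and cartilage were lower too. Of 21 skeletal muscle genes, 19 fell (20 adjusted over the list alone), with a median of -2.72 (adjusted p = 5.48e-09; adjusted p = 0.261 with an estimated correlation). Ckmt2, the mitochondrial creatine kinase of muscle, fell by 4.03 (SE 0.51). The muscle list's mean signal was 11.78, 13.48 and 12.52 on controls A, B and C, and between 9.69 and 10.17 on the infected arrays. That of the bone and cartilage list was 8.72, 9.60 and 8.78 on the controls, and between 6.97 and 7.30 on the infected arrays. Control B, with the lowest mean of the hair list among controls, had the highest of both these lists. Among 15 adipocyte and lipogenesis genes 10 fell (11 adjusted over the list alone), with a median of -2.19 (adjusted p = 7.53e-06; adjusted p = 0.119 with an estimated correlation). Elovl3, a fatty acid elongase of skin glands and brown fat, was detected on no infected array and was at least 27.6-fold lower, and Adig, a gene of fat cell differentiation, fell by 4.53 (SE 0.37). In the bone and cartilage list 6 of 7 members fell, 6 also when adjusted over the list alone, with Chad, a cartilage matrix protein, lower by 14.4-fold and a list median of -1.77 (adjusted p = 0.00169; adjusted p = 0.257 with an estimated correlation). Erythroid genes did not pass as a list (median -1.82, adjusted p = 0.0697), although 4 of 6 fell, 4 also when adjusted over the list alone, and Slc4a1, the anion exchanger of red cells, fell by 3.66 (SE 0.43). With the preset correlation, the erythroid list passed without control A (adjusted p = 0.0204) and without infected C (0.0236). It also passed with median scaling (0.00789), with no scaling (0.00302) and with array weights (0.0338). With an estimated correlation its adjusted p in the main fit was 0.451.

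Peripheral nerve is a tissue that Mycobacterium leprae infects, and its markers did not move as a list. Of 13 Schwann cell and myelin genes, 1 rose and 3 fell, 1 and 3 also when adjusted over the list alone, with a median of -0.69 (adjusted p = 0.366). Mbp, which encodes myelin basic protein, and Sox10, a transcription factor of Schwann cells, fell by 1.65 and 1.41, and Fa2h, a fatty acid hydroxylase also active in skin, fell by 3.745 (SE 0.60), or by 3.05 without control A. The median was -0.415 without control A. Mag, a myelin glycoprotein gene, rose by 4.08 ± 0.33 (adjusted p = 0.000178). A second probe for Mag was detected on 0 of 6 arrays and had a log2 fold change of 0.15. Pmp22, with low signal on control A, had a log2 fold change of 2.95 ± 1.46, or 1.07 without that array, and passed in neither case.

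Lists of metabolism and proliferation were measured too. In the iron handling list 7 of 11 members rose and 1 fell, 7 and 1 also when adjusted over the list alone, with a median of 1.40 (adjusted p = 0.00727; adjusted p = 0.126 with an estimated correlation). The ferritin heavy chain gene Fth1 rose by 3.70 ± 0.62, or 3.05 without control A, and the iron exporter gene Slc40a1 fell by 2.14. Of 14 cell cycle genes 7 fell (8 adjusted over the list alone), with a median of -1.004 (adjusted p = 0.00173; adjusted p = 0.271 with an estimated correlation), and the mitotic kinase gene Plk1 fell by 1.67 (SE 0.21). Of 16 genes of mitochondrial respiration 9 fell, 9 also when adjusted over the list alone, with a median of -0.64 (adjusted p = 0.00263; adjusted p = 0.204 with an estimated correlation), and Idh3a, an enzyme of the citric acid cycle, fell by 1.501 (SE 0.26; a second probe had -1.37). Glycolysis genes were not shifted as a list (median 0.42, adjusted p = 0.0711, or 0.391 with an estimated correlation). With the preset correlation the adjusted p was 0.032 without control B, 0.039 without infected B and 0.00881 with no detection filter. Of 11 members 4 were higher, 4 also when adjusted over the list alone, among them the regulatory enzyme gene Pfkfb3 (1.33 ± 0.23). Reference genes were not shifted either (median 0.20, adjusted p = 0.753, with a median of 0.06 without infected A). Of 9 of them 2 fell (2 rose and 2 fell without control A), or 1 when adjusted over the list alone, namely Rpl13a by 1.00 (SE 0.18) and Tbp by 0.95. The calls for Plk1, Idh3a and Rpl13a were lost with no scaling between arrays (adjusted p = 0.0662, 0.0877 and 0.159), and that for Rpl13a also with median scaling (adjusted p = 0.0618).

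**Figure D3:**
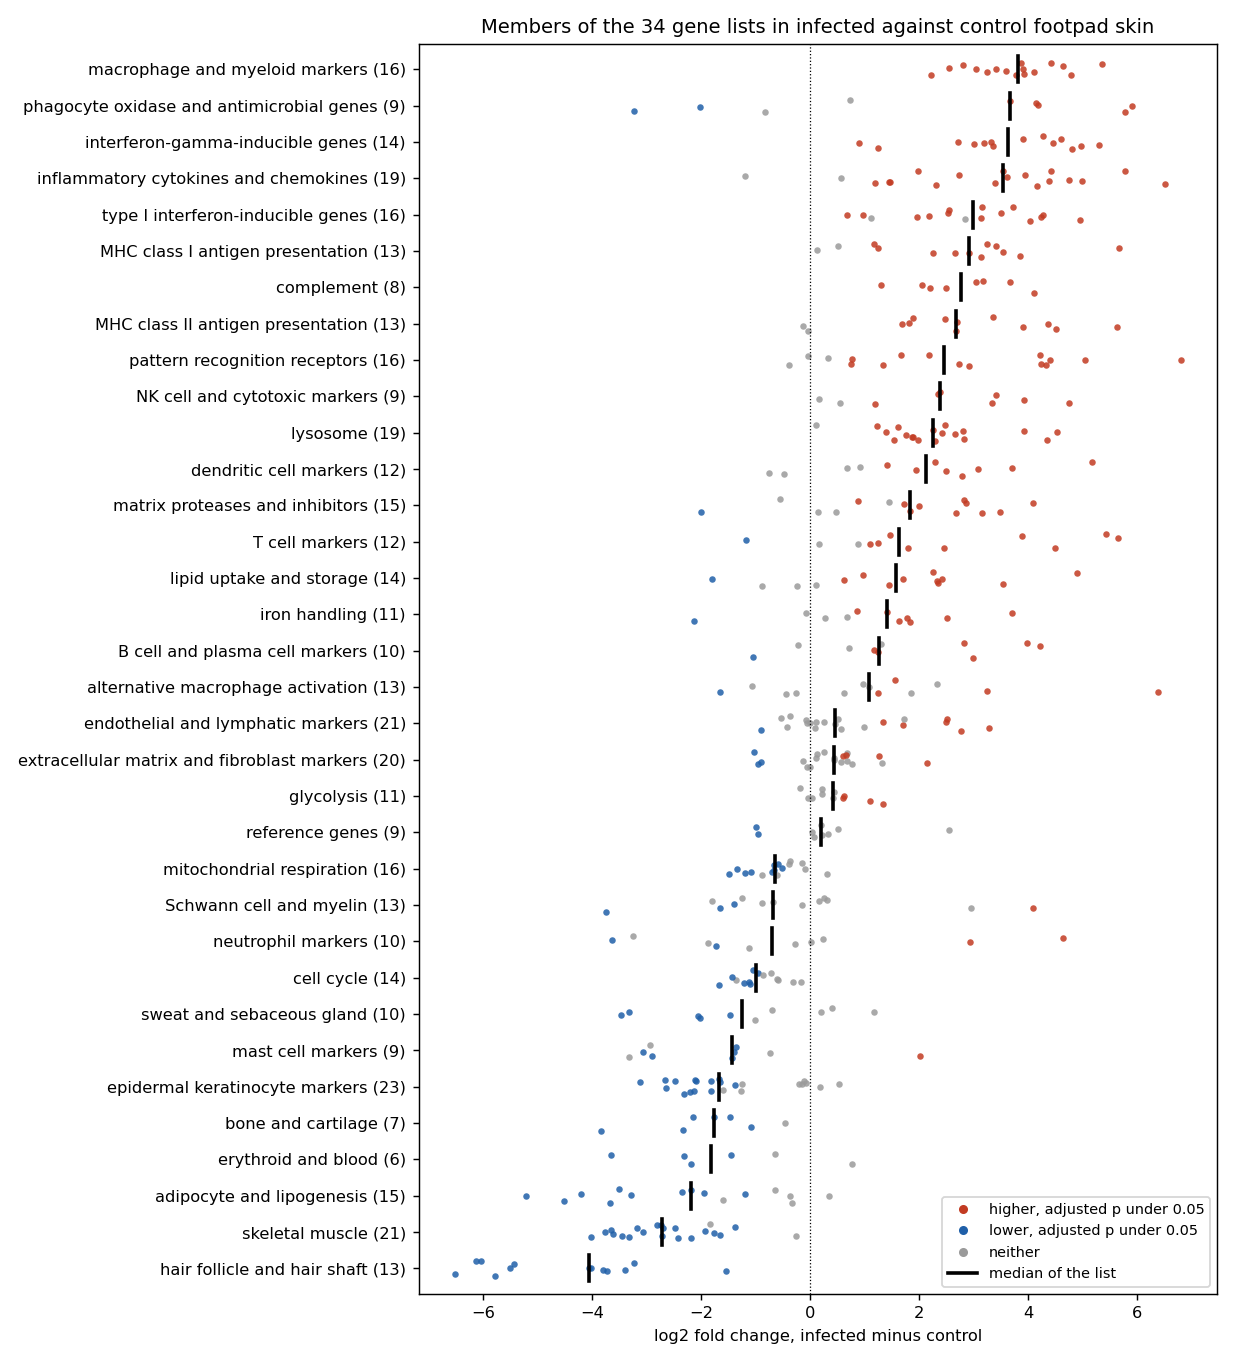
Log2 fold change, infected minus control (horizontal axis), of the tested members of the 34 gene lists, 1 point per gene with the number tested in brackets, red for higher and blue for lower at adjusted p under 0.05, and a black bar at each list's median. Medians ranged from 3.82 for macrophage and myeloid markers to -4.06 for hair follicle and hair shaft.

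Over the 34 lists, 18 were shifted up and 9 down by camera with a preset correlation of 0.01 between genes, and 7 were not called. With a correlation estimated for each list, 0 lists were called in either direction by camera, with 12 up and 1 down at an unadjusted p under 0.05, and fry, which tests each list by itself, called 20 up and 9 down. Of all genes tested, 53.9% had no overlap between the groups, against 10% by chance. The median residual SD, after moderation by eBayes, was 0.34 on the log2 scale. The split of calls depended on the scaling between arrays: 47.8% of calls were higher after quantile normalization, 60.8% (1618 higher and 1044 lower) after median scaling, and 69.0% (1789 higher and 803 lower) with no scaling, where the median of all genes moved from -0.05 to 0.13 and 0.29. The number of arrays, 3 per group, limits the precision of each value.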

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

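The tests of explanations in this part were chosen after the results were seen, as was the fit of unnamed probes.

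Probes without a gene name here took no part in the comparison of genes, and some of them differed between the groups too. Of 3683 such detected probes, 563 were higher and 469 were lower in infected skin by the same test, and 227 of those that were higher were detected on no control array. Their log2 fold changes reached 7.40 and -7.61. Which transcripts they measure was not analysed here.

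No other split of the 6 arrays into 3 and 3 called a gene after adjustment: the real split called 3437 genes and the highest of the other 9 called 0, with at most 264 genes at an unadjusted p under 0.05. Each other split puts control and infected arrays together on both sides. The difference between the groups then adds to the spread within each side, so few calls are left in such splits whatever the source of that difference. The real split was 1 of 10, so these splits cannot give a share under 0.1.

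Control A departed from controls B and C, with 276 of 7108 bright probes at least 8-fold lower and 3 at least 8-fold higher. A difference in tissue or in the amounts of transcripts would move separate probes of a gene together. Over 290 genes with 2 bright probes the correlation of their departures was 0.127 (upper 95% bound 0.244). For the difference between controls B and C it was 0.633 (lower bound 0.415). These values argue against a difference in transcript amounts as the main source. They do not bear on RNA quality, which can act unequally on separate probes of a gene and was not tested. Control A had the fewest detected probes, 12386. The scaling between arrays is argued against by the values before it, where 200 bright probes lay at least 8-fold below the array's own median departure on control A and 30 on control B. Loss of signal at single probes may account for the departure: of 26 genes with a probe at least 8-fold lower, the other probe lay within 2-fold in 19. What lowered those probes was not tested.

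Lists of resident tissue had different medians. Dilution of all resident tissue by cells that carry no matrix transcripts would lower matrix genes about as far as muscle genes. The median of the matrix list was 0.4321, with quartiles of -0.03 and 0.67, against -3.33 and -1.93 for muscle. These values cannot decide on dilution by a lesion whose own cells express matrix genes, because such cells would hold the matrix list up. The scaling between arrays is argued against by the medians without it, -2.638 for muscle, -3.70 for hair and -1.585 for keratinocytes. With the preset correlation, camera gave adjusted p = 2.02e-18, 4.26e-11 and 2.43e-09 there. With an estimated correlation these lists were not called in the main fit (adjusted p = 0.261, 0.278 and 0.211). With no other change in tissue content, a single difference in cutting depth would move muscle and keratinocyte genes in opposite directions. Both lists were lower, with upper quartiles of -1.93 and -0.7365, which argues against cutting depth acting alone as the source of the 2 falls. Leukocyte genes rose, however, and a shallower cut together with added cells could lower both lists, so these values cannot decide on that combination. Of the 23 keratinocyte markers 14 fell and 9, among them Krt14 and Lor, did not pass. For the muscle list (mean change -2.62) or the hair list (median -4.056) alone, cutting depth cannot be told apart from an effect of infection, because no label gives the depth of the cut. Loss of hair follicles and muscle with infection stays an open, untested explanation.

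T cell markers rose in mice that lack a functional thymus. A single array is argued against as the source, since at least 9 of the 12 markers were higher in every fit that left out 1 array. NK cells as the only source would leave markers with little expression in NK cells at the control level. Of 6 such markers 4 were tested (Cd28, Trat1, Cd5 and Cd8b1), and 2 rose, Cd28 at least 1.77-fold and Trat1 at least 1.53-fold. Both had infected means, 6.72 and 6.51, within 1 unit of the mean detection floor of 5.75. Without control A all 4 rose, Cd5 by 1.15 and Cd8b1 by 0.57. The Cd8b1 probe was bright in both groups (means of 11.12 in control and 11.28 in infected skin), although Cd3e and Cd3g were detected on no control array. Its signal therefore cannot be read as that of T cells. NK cells alone and a mixture with T cells cannot be told apart by these values. T cells that mature outside the thymus may contribute, which was not tested.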

How the results depend on the processing

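The fits with repeated rows kept and with a replicate block were chosen after seeing the data. Of the counts under other settings, 120 values stayed within 1.5 times the reported ones and 8 did not: 1054 higher and 1026 lower genes at an adjusted p under 0.01; 1044 lower genes with median scaling; 803 lower, and 779 at least 2-fold lower, with no scaling between arrays; 1156 lower genes without infected C; and 0 lists up and 0 down with an estimated correlation (12 and 1 at an unadjusted p under 0.05; fry called 20 and 9, camera on ranks 16 and 8). Apart from the stricter threshold, the cause was not tested. Keeping repeated rows gave 1600 higher and 1874 lower genes. Leaving out 1 array gave 1173 to 2235 higher and 1156 to 2185 lower genes (1068 to 1477 and 1050 to 1418 at least 2-fold), the lowest without infected C and the highest without control A, with 17 to 19 lists up and 8 to 10 down. Of values of named genes 1168 kept their call and 10 lost it; of list medians 620 kept it, 12 lost it, 13 gained it and 1 reversed, the Schwann cell and myelin median, 0.15 with the stricter detection filter and not called in either case. The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.06, 0.04 and -0.13 in the authors' values, not every array correlated best with its own number, where the replicate block gave 1435 higher and 1585 lower genes against 1567 and 1829 without it. Calls gained were those of alternative macrophage activation (no detection filter, all probes, without infected B or C; adjusted p 0.0222 to 0.0401), erythroid genes (6 settings, 0.00302 to 0.0338) and glycolysis (no detection filter, without control B or infected B; 0.00881 to 0.039). No detection filter tested 17249 genes and called 1526 higher and 1614 lower.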

Other observations

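The families below and the values of Mag and Cd22 were chosen after the results were seen. Genes were grouped by the letters that open their symbols, and the 129 families with at least 8 tested genes were each tested with camera: 9 were shifted up and 7 down, and 0 with an estimated correlation (7 at an unadjusted p under 0.05). All 10 tested Sprr genes, which encode small proline-rich proteins of the cornified envelope, fell (median -2.66, adjusted p = 7.2e-05; adjusted p = 0.567 with an estimated correlation), as did 14 of 15 Lce genes of the late cornified envelope (median -2.02, adjusted p = 1.05e-06; adjusted p = 0.645 with an estimated correlation). Of 13 kallikrein genes, which encode serine proteases, 9 fell (median -1.76, adjusted p = 0.0224; adjusted p = 0.732 with an estimated correlation), among them Klk6, 19.5-fold lower, and of 11 Serpinb genes, which encode protease inhibitors, 8 fell (median -1.87, adjusted p = 0.00264; adjusted p = 0.567 with an estimated correlation). None of the Sprr or kallikrein genes was in a fixed list, and 1 Lce gene and 1 Serpinb gene were.

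Other families rose. Of 9 Parp genes, which encode ADP-ribosyltransferases, 5 rose and none fell (median 1.13, adjusted p = 0.0284; adjusted p = 0.714 with an estimated correlation), Parp14 by 3.25. Of 9 genes whose symbols open with Man, most of them mannosidases, 7 rose (median 1.14, adjusted p = 0.0108; adjusted p = 0.567 with an estimated correlation). The families named here kept their direction under all 3 other scalings between arrays and their call without control A. Factor VII, F7, rose beside F10 and was at least 27.5-fold higher (adjusted p = 0.000696).

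Mag lies next to Cd22, a B cell gene, among protein-coding genes in the RefSeq annotation. Mag rose by 4.08 ± 0.33 on the log2 scale and Cd22 was at least 8.83-fold higher, while Cd79a and Cd79b, which encode chains of the B cell receptor complex, rose, the first at least 1.27-fold and the second 2.37-fold, while the log2 fold change of Cd79b went from 1.25 to 0.81 without control A.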
